A study of Drosophila melanogaster and Drosophila simulans and Drosophila erecta with 10 samples.

How the data were processed

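RNA-seq was done on testes of D. melanogaster and D. simulans, control and miR-983 knockout, with 2 libraries for each genotype and species (8 in all), and small RNA sequencing on testes of D. erecta and D. sechellia (2 libraries in all). The series' design text calls the 2 libraries of a genotype biological replicates. Per the labels' protocols, tissue was dissected on dry ice, RNA was taken up in Trizol, and small RNAs of 18 to 30 nt were cut from a gel. TopHat, a spliced-read aligner, is named in the submitters' processing notes without a version. The genome builds, annotation, read counter, adapter trimming and handling of strand and multi-mapping reads are not given in the sources used here.

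The gene tables hold log2 expression values that the authors deposited, 1 column per library. The quantity under the logarithm, any pseudocount and the scaling between libraries are not given, and the lowest value is 1.0007. The log2 fold change the authors deposited equals the mutant mean minus the control mean of these columns within 2e-06. The authors' tables also mark predicted targets of each miR-983 arm (TargetScan and PITA) and genes past p 0.05 by DESeq2, per the file headers. The small RNA tables hold a raw read count per microRNA and precursor and an RPM value, both deposited by the authors. The RPM divides by a sum that counts a microRNA once per precursor, which counts 10.9% of D. erecta reads and 0.68% of D. sechellia reads again. All 86 and 80 entries were therefore reduced to 78 and 72 distinct microRNAs, keeping the highest count among copies of the same microRNA, and levels were given as RPM of the new sums. No table column was left unmapped (0 columns).

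Genes were tested in each species separately with limma 3.58.1 in R 4.3.3, with the empirical Bayes trend, two-sided, on the log2 values as deposited, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test had been fixed for unlogged values with a pseudocount of 1. The tables were already on a log scale, so no pseudocount was added. Fold changes are on this scale and can understate the change of low genes. The fixed filter, a mean of at least 1 on the linear scale, removed no gene, so the alternative without a filter is void. The replicate numbers were not used as a block, since they share only a number. Gene lists (19, fixed in advance, covering germline stages, sperm genes, Y-linked genes, somatic testis, accessory gland, ejaculatory bulb, muscle, fat body, antimicrobial, heat-shock, neural, small RNA pathway, detoxification, ribosomal and oxidative phosphorylation genes) were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it; fry tests a list against no change, not against other genes. With 2 libraries per genotype the estimated-correlation test has few degrees of freedom and can hardly pass after adjustment. An estimated correlation above the preset also raises its p, and for such a list the preset p may be too small. A list that does not pass the estimated-correlation test is not shown to be unchanged. Of the D. melanogaster identifiers 7195 of 7326 matched a symbol, and of the D. simulans identifiers 0 of 6744. The D. simulans gene lists, the test of a difference between species and the correlation of effects between species were therefore not run. The planned search for seed sites needs a genome that was not used here; the authors' target columns took its place, tested with camera and adjusted over the 3 sets of a species. The Fisher tests of calls among targets were added after the data were examined, and their p-values were adjusted over 12 tests. Their rerun in D. simulans under each setting was added then too, without adjustment. Gene order was taken from assembly Release 6 plus ISO1 MT, in which 7181 tested genes could be placed, and was used only for neighbourhood, overlap and gene class.

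Genes were named by a rule fixed before the data were examined: the 12 largest rises and 12 largest falls past the threshold whose mutant libraries lie on the same side of both controls and whose mean is at least 2 on the linear scale in 1 group, up to 4 members of each list by smallest p, the miR-983 genes, their neighbours, white and yellow, the 10 most abundant microRNAs of each library, listed members of the young testis clusters, and up to 8 microRNAs per direction with at least a 4-fold ratio and 100 RPM. In D. simulans only the 2 largest changes per direction are printed, as identifiers without symbols. Predicted targets are named by the rule for lists; that use of it came after the data were examined. Further heat-shock genes (Hsp70Bb, Hsp26, Hsp23, Hsp67Bc, Hsc70-3, Hsc70-4, Hsc70-5, Hsp60A, Hsp27, DnaJ-1, Hsp67Ba and Hsp83) are named to describe that list and were chosen after their values were seen. MicroRNAs with counts have exact binomial intervals at 95%, computed with SciPy 1.17.1 in Python 3.11.15; no test was made between the 2 small RNA libraries. Ratios were not formed where the tables name arms or copies differently (miR-184, miR-281, miR-306, miR-iab-4 and the miR-310 cluster). Values for such microRNAs are shares only.

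The gene test was tested on simulated data built from the real means and residual spread, with 200 changed genes. In D. melanogaster (7326 genes) it recovered 92.3% of changes of 0.5 on the log2 scale and 100% of changes of 1 and 2, and 16 of its calls were false (7.58%). In D. simulans (6744 genes) it recovered 87.1%, 100% and 100%, with 11 false calls (5.42%). The simulated noise was independent between genes and carried no shift with level, and no change below 0.5 was simulated. These rates therefore do not cover smaller changes, which made up 1554 of the 2091 D. simulans calls. Alternatives tried were a replicate block, leaving out each library, median ratio scaling, quantile normalization, a mean of at least 5 on the linear scale, a pseudocount of 0.1 in place of an assumed 1, limma without trend, a 2-fold minimum, and other scalings of the microRNA counts. Cyclic loess, 1 gene per set of identical values, the heat-shock list without its Hsp70 copies and the RPM as deposited were added after the data were examined. The authors' read depth for the RNA-seq libraries is unknown.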

Results

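Gene expression was measured by RNA-seq in testes of 3- to 5-day-old adult flies reared at 25 °C. In each of 2 species, Drosophila melanogaster and Drosophila simulans, 2 control libraries were set against 2 libraries from flies carrying a miR-983 knockout. Small RNAs of 18 to 30 nt were sequenced from wild-type testes of Drosophila erecta and Drosophila sechellia, with 1 library per species. There are log2 expression values for 7326 genes of D. melanogaster and 6744 of D. simulans, with 1 value per library. Sequencing depth of the RNA-seq libraries is unknown, since no read totals stand beside the log2 values. Every listed value is above 1 in every library, so a gene silent in 1 genotype would not be listed. The small RNA tables hold read counts, which sum to 2974235 reads in D. erecta and 2988430 in D. sechellia once each microRNA is counted a single time.

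The deleted gene itself could not be followed in these tables: they hold 0 entries under the symbols of the miR-983 genes, white or yellow in D. melanogaster. The 4 tested genes closest to the miR-983 genes in gene order (assembly Release 6 plus ISO1 MT) did not pass the test. CG12693 had a log2 fold change of 0.06 ± 0.06 (SE), NO66 of -0.10 ± 0.08, rb of 0.03 ± 0.11 and CHOp24 of -0.03 ± 0.10, with limma adjusted p between 0.708 and 0.951.

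The first comparison asked which testis transcripts differ between miR-983 mutants and controls in D. melanogaster. Of 7326 genes 167 changed, 77 higher and 90 lower in the mutant (limma, Benjamini-Hochberg adjusted p under 0.05, 2 libraries per genotype). Among them 32 changed by at least 2-fold (20 higher, 12 lower). The balance of directions depended on the scaling, with 81 higher and 80 lower after median ratio scaling. The median absolute log2 fold change of the 167 genes was 0.62, against 0.07 over all genes. The median difference was 0.08 between the control replicates and 0.10 between the mutant replicates. These are differences of single libraries, while a fold change compares means of 2, so 0.07 is not shown to lie within replicate spread. The count depended on single libraries: it was 304 without control replicate 1 and 259 without control replicate 2. With a replicate block the count was 503 (213 higher, 290 lower). The 2 genotypes did not overlap in 42.3% of genes, where chance gives 33.3%. An unadjusted limma p under 0.05 was reached by 930 genes, so differences may extend beyond the 167. The authors' deposited table marks 121 genes as past p 0.05 by DESeq2, of which 106 are among the 167.

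Transcripts without a coding function led the changes. The largest rise was CR33319, a pseudogene, from a log2 value of 3.52 ± 0.20 (SD, n = 2) in controls to 6.89 ± 0.32 in mutants, a 10.3-fold difference (limma adjusted p = 0.000102). The long non-coding RNAs lncRNA:CR43414 (log2 fold change 3.02 ± 0.26, SE), lncRNA:CR41443 (2.23 ± 0.12), lncRNA:CR43810 (1.43 ± 0.09) and lncRNA:CR43974 (1.41 ± 0.09) rose too, as did the antisense RNA asRNA:CR45822 (1.18 ± 0.11) and the pseudogene CR10102 (1.15 ± 0.08). Protein-coding genes among the 12 largest rises were CG7194 (1.91 ± 0.10), CG44355 (1.41 ± 0.16), CG4627 (1.30 ± 0.11), CG42828 (1.16 ± 0.09) and DCTN6-p27 (1.16 ± 0.09), a subunit of the dynactin complex. These 12 rises had limma adjusted p between 0.000102 and 0.0051.

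The largest fall was lncRNA:CR43839, from 3.45 ± 0.09 (SD, n = 2) in controls to 1.24 ± 0.06 in mutants, with a log2 fold change of -2.21 ± 0.09 (SE; limma adjusted p = 0.000102). lncRNA:CR44091 (-1.55 ± 0.12), lncRNA:CR45410 (-1.14 ± 0.10) and lncRNA:CR44919 (-1.06 ± 0.10) were also lower. Mccc1, which encodes a subunit of the leucine-degrading enzyme methylcrotonoyl-CoA carboxylase, changed by -1.30 ± 0.12, and Pyroxd1, a predicted oxidoreductase, by -1.26 ± 0.08. CG31269 and the antisense RNA asRNA:CR44238 overlap each other and both changed by -1.29. CG30099 and CG10747 each changed by -1.06. GILT3, of the lysosomal thiol reductase family, changed by -1.01 ± 0.15, and the inducible chaperone Hsp70Aa by -1.03 ± 0.13. These 12 falls had adjusted p between 0.000102 and 0.0169. Of the 24 genes named for size, 13 overlap another annotated gene, and the sources used here do not say whether reads were assigned by strand, so the 13 values are uncertain.

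Many heat-shock genes were lower in the mutant testes. The list passed camera with a preset correlation (adjusted p = 9.02e-14 over 18 lists), but not with an estimated correlation (adjusted p = 0.422) or fry (adjusted p = 0.179). Unadjusted, p was 0.0235 for camera with an estimated correlation and 0.00995 for fry. The estimated-correlation test has few degrees of freedom with 2 libraries per genotype, so its failure to pass cannot decide the question. Even the accessory gland list of 1 gene, with no correlation to estimate, went from an unadjusted camera p of 0.092 to 0.234. Of 19 measured members of the heat-shock list, 11 fell and none rose (13 fell when adjusted over the list alone), with a median log2 fold change of -0.44. The 5 Hsp70 copies fell together, by 0.96 for Hsp70Bb up to 1.03 for Hsp70Aa on the log2 scale, and their reads may be shared between near-identical copies. Members other than these 5 copies also fell. Hsp68 changed by -0.52 ± 0.06 (SE), the small heat-shock proteins Hsp22 by -0.53 ± 0.06, Hsp26 by -0.43 ± 0.06, Hsp23 by -0.44 ± 0.07 and Hsp67Bc by -0.68 ± 0.10, and the co-chaperone starvin (stv) by -0.69 ± 0.08. The chaperones Hsc70-4 (-0.01 ± 0.10), Hsc70-5 (0.01 ± 0.06) and Hsp60A (-0.06 ± 0.09) did not pass, nor did Hsp27 (-0.28 ± 0.07), DnaJ-1 (-0.21 ± 0.08), Hsp67Ba (-0.16 ± 0.10), Hsp83 (-0.14 ± 0.11) or Hsc70-3 (0.04 ± 0.07). The mean log2 value over the list was 5.17 and 5.21 in the controls and 4.74 and 4.69 in the mutants. Hsp23 lost its call without mutant replicate 1 (adjusted p = 0.0601) and without mutant replicate 2 (adjusted p = 0.069).

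**Figure D1:**
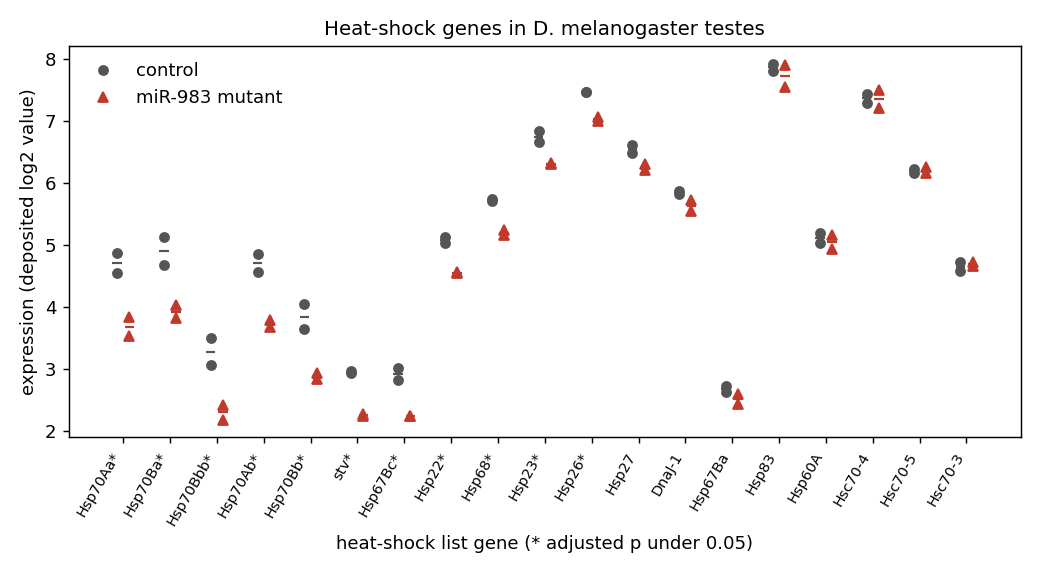
Deposited log2 expression (vertical axis) of the 19 measured heat-shock list genes (horizontal axis) in D. melanogaster testes; circles are the 2 control libraries, triangles the 2 miR-983 mutant libraries, short lines the group means, and asterisks mark adjusted p under 0.05. The 11 marked genes lie lower in both mutant libraries than in both controls, while Hsc70-4, Hsc70-5 and Hsc70-3 overlap.

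Fat body genes were the other list past the camera threshold with a preset correlation (adjusted p = 0.0104). The list did not pass with an estimated correlation (adjusted p = 0.987) or fry (adjusted p = 0.534). Its estimated correlation was 0.85, above the preset 0.01, so the preset p may be too small. Of 4 measured members, 2 rose: NLaz, a lipocalin, by 0.62 ± 0.08 (SE; limma adjusted p = 0.00771) and Tsf1, a transferrin that binds iron, by 0.80 ± 0.11 (adjusted p = 0.0103); both also passed when adjusted over the list alone (2 genes). The odorant-binding protein genes Obp99a (0.02 ± 0.08) and Obp44a (-0.00 ± 0.10) did not pass. Without mutant replicate 2 the list's adjusted p was 0.152 by camera. That library also stood apart in Acp95EF, the 1 measured of 32 accessory gland genes, at 6.34 against 4.42 in mutant replicate 1 and 4.16 and 4.12 in the controls (limma adjusted p = 0.343; it passed adjusted over the list alone, 1 gene). As a list of 1 gene it did not pass camera (adjusted p = 0.414, or 0.987 with an estimated correlation). With 1 library left out, the log2 fold change of Acp95EF ranged from 0.29 to 2.20, so its size depended on mutant replicate 2.

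Few of the measured genes of sperm production passed the test. None of 13 measured meiotic arrest genes, 14 comet and cup genes of late transcription or 29 sperm chromatin and tail genes passed (0 genes). Nor did any of 9 genes of meiotic entry or 6 early germline genes. Over all 7326 genes 2.28% were called, and 930 had an unadjusted p under 0.05. With so low a share, 0 calls in groups of this size does not set them apart from other genes. The smallest p in these groups belonged to mia, a testis-specific TAF homolog, at 0.45 ± 0.09 (limma adjusted p = 0.0537; it passed adjusted over the list alone, 1 gene), t-cup at -0.20 ± 0.06 and the protamine ProtB at 0.25 ± 0.08. Of 4 bromodomain coactivator genes, tbrd-3 rose by 0.40 ± 0.07 (adjusted p = 0.0294), whereas tbrd-2 was at -0.10 ± 0.07; tbrd-3 lost its call without any 1 of control replicate 2 and the mutant replicates (adjusted p = 0.0647 to 0.0765). Among 20 small RNA pathway genes, tud, which encodes the germ granule protein Tudor, fell by 0.50 on the log2 scale (SE 0.09, adjusted p = 0.033), and del was at -0.42 ± 0.11 (adjusted p = 0.12); both passed adjusted over the list alone (2 genes). The call of tud was lost without control replicate 1 (adjusted p = 0.0581) and without either mutant replicate (0.0675 and 0.0926). Of 87 ribosomal protein genes 2 fell, both paralogs of canonical subunits: RpL22-like by 0.46 (SE 0.08, adjusted p = 0.0268) and RpL37-2 by 0.32 (SE 0.06, adjusted p = 0.0479). RpL22-like lost its call without mutant replicate 1 (adjusted p = 0.0791), and RpL37-2 lost its call without any 1 library (0.0513 to 0.142). The ribosomal list as a whole did not pass camera (adjusted p = 0.945; 0.991 as an adjusted p with an estimated correlation), and passed upward without mutant replicate 1 (0.000706) and downward without mutant replicate 2 (0.00133). None of 78 oxidative phosphorylation genes passed (0 genes).

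Markers of the remaining cell types and states were few among the measured genes. Muscle had 8 measured members, somatic testis cells 4, Y-linked genes 3, detoxification 9, and the ejaculatory bulb and the antimicrobial list 1 each, with 0 passing in any of them; none of the 13 neural markers was listed. Adjusted over the list alone, 1 Y-linked gene (FDY, 0.29 ± 0.09) and 1 somatic gene (MtnA, a metallothionein, 0.35 ± 0.07) passed.

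A microRNA lowers its targets, so its loss was asked to raise genes with predicted sites. In D. melanogaster the authors' deposited table marks 393 genes as TargetScan targets of miR-983-5p, 350 as TargetScan targets of miR-983-3p and 294 as PITA targets of miR-983-5p. Their mean log2 fold change differed from that of other genes by 0.013, -0.003 and 0.006 (camera adjusted p = 0.82 for each of the 3 sets). In a comparison chosen after the data were seen, the median of the first set, 0.0065, lay above 95% of level-matched lists (-0.0255 to 0.0013). The medians of the other sets lay within their ranges. Such lists treat genes as independent. Few targets changed: 3 rose and 3 fell in the first set, 3 and 4 in the second, and 1 and 3 in the PITA set. foi, a zinc transporter gene present in all 3 sets, rose by 0.82 ± 0.10 (SE; limma adjusted p = 0.00689), CG17048 by 0.92 ± 0.07 and CG2617 by 0.87 ± 0.09. Other predicted targets moved the opposite way: Pyroxd1 and Hsp67Bc (values above), RNaseX25, a ribonuclease, at -0.84 ± 0.08, DCTN1-p150, the large dynactin subunit, at -0.64 ± 0.09, and CG31677 at -0.65 ± 0.08, each past the threshold. tud, also a predicted target in all 3 sets, fell by 0.50 (value above). Without control replicate 2, the 2 miR-983-5p set means turned to -0.0048 and -0.0137, and without control replicate 1 the miR-983-3p mean turned to 0.0231.

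In D. simulans 2091 of 6744 genes changed, 1132 higher and the others lower in the mutant (limma, adjusted p under 0.05, 2 libraries per genotype), and 87 of them by at least 2-fold. The median absolute log2 fold change of the 2091 genes was 0.37, and 0.16 over all genes, against a median difference of 0.07 between control replicates and 0.10 between mutant replicates. The genotypes did not overlap in 68.5% of genes, where chance gives 33.3%. The test rests on the spread between the 2 libraries of each genotype. Stock background and handling were not tested in D. simulans and cannot be told apart from genotype there. The D. simulans identifiers have no symbols in the sources used here, so single genes are given by identifier. FBgn0188568 rose from 2.69 ± 0.08 (SD, n = 2) to 5.43 ± 0.00, a 6.71-fold difference (limma adjusted p = 6.46e-10), and FBgn0189817 rose from 1.79 ± 0.44 to 4.13 ± 0.01. FBgn0269854 fell from 4.31 ± 0.03 to 1.76 ± 0.03, which is 5.86-fold lower (adjusted p = 8.19e-09), and FBgn0269623 from 3.85 ± 0.22 to 1.60 ± 0.10. The authors' deposited table marks 1206 genes as past p 0.05 by DESeq2, and 1164 of these are among the 2091. The count was 1241 without control replicate 1 and 1370 without control replicate 2. The fold change followed expression level: its median was 0.10 in the lowest of 10 groups of genes ranked by level and -0.05 in the highest, with 74 rises and 28 falls in the lowest and 98 rises and 189 falls in the highest. The trend was steeper in mutant replicate 1 (0.17 and -0.07 against the controls) than in mutant replicate 2 (0.03 and -0.03). Mutant replicate 1 has 52 genes with a value under 1.25, against 144 in mutant replicate 2 and 176 and 178 in the controls. Without mutant replicate 2 the calls were 1515 higher and 976 lower, and without mutant replicate 1 they were 779 higher and 823 lower.

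Predicted miR-983 targets leaned upward in D. simulans without passing the test. The 284 TargetScan targets of miR-983-5p lay 0.068 above other genes on the log2 scale (camera adjusted p = 0.0744), the 217 targets of miR-983-3p 0.072 above (0.0744) and the 213 PITA targets 0.056 above (0.0744). The correlations estimated in the 3 sets were 0.18, 0.15 and 0.21, above the preset 0.01, so the preset p may be too small. With an estimated correlation the adjusted p was 0.684 for each set. With fry, which tests a set against no change and not against other genes, it was 0.219. The differences were smaller after cyclic loess (0.047, 0.057 and 0.037; adjusted p 0.241, 0.157 and 0.241), a setting chosen after the data were seen. Relative to other genes, each of the 3 target means was higher in both mutant libraries than in both controls; an exact permutation test of 2 against 2 libraries cannot give a p below 0.333. Falls were fewer among targets than among other genes. In the miR-983-5p TargetScan set 22 genes fell (7.75%, against 14.5% of other genes; Fisher's exact test, two-sided, adjusted p = 0.00546 over 12 tests) while 58 rose (20.4% against 16.6%, adjusted p = 0.312). The falls were 7.37% against 14.4% for miR-983-3p (adjusted p = 0.00844) and 5.63% against 14.5% for the PITA set (adjusted p = 0.00103). These tests treat genes as independent, which they are not. The falls numbered 6 without control replicate 1 and 8 without control replicate 2 in the first of these sets (2.11% and 2.82%, against 8.92% and 8.85% of other genes), 7 and 10 without control replicate 1 and 2 in the miR-983-3p set (3.23% and 4.61%, against 8.81% and 8.73%), 5 without either control in the PITA set, and 19 there after quantile normalization. The rises numbered 34, 16 and 15 in the 3 sets without control replicate 1, and 35, 22 and 21 without mutant replicate 1. Without control replicate 2 they numbered 42, 26 and 22, and without mutant replicate 2 they numbered 77, 63 and 53. Targets were expressed at a lower level than other genes (mean log2 value 3.03 against 3.76 in the miR-983-5p TargetScan set), where falls were fewer. Level-matched lists of other genes gave 32.2 falls on average for that set (95% of lists 23 to 42), 26.5 for miR-983-3p (18 to 36, against 16 seen) and 24.3 for the PITA set (16 to 33, against 12 seen). The same lists gave 46.4 rises for the miR-983-5p TargetScan set (35 to 59, against 58 seen), 35.3 for miR-983-3p (25 to 46, against 42 seen) and 34.1 for the PITA set (24 to 45, against 37 seen). Without mutant replicate 2 all 3 sets passed camera (adjusted p 0.0193 to 0.0217), and without mutant replicate 1 the adjusted p was 0.222 in each. A difference between the species in this shift was not tested, because their genes could not be matched.

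**Figure D2:**
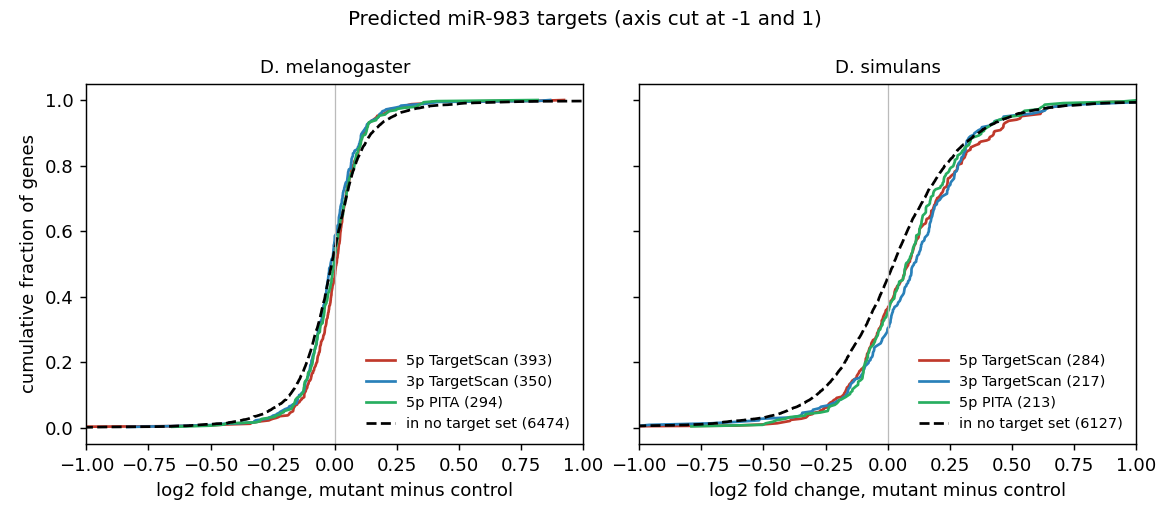
Cumulative fraction of genes (vertical axis) by log2 fold change of mutant against control (horizontal axis, drawn from -1 to 1) in D. melanogaster (left) and D. simulans (right); solid lines are the 3 sets of predicted miR-983 targets with their gene numbers, and the dashed line is the genes in none of the 3 sets. The lines cross near 0 in D. melanogaster, and in D. simulans the target lines lie to the right of the dashed line below and around 0. In D. simulans the set means exceed those of all genes outside each set by 0.056 to 0.072.

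The small RNA libraries show which of the listed microRNAs were most abundant in testes of the other species, with 1 library each and so no replicate check. Shares are of reads counted for the 78 listed microRNAs in D. erecta and the 72 in D. sechellia. MicroRNAs that are not listed could rank higher. The 10 most abundant listed microRNAs took 81.3% of these reads in D. erecta and 84.7% in D. sechellia. In D. erecta miR-263a led with 27.1% of reads (95% exact binomial interval 27.03 to 27.13), followed by miR-281-2-5p (11.4%), miR-312 (10.8%), miR-8 (7.50%), miR-184-3p (6.49%), miR-10 (5.98%), let-7 (3.72%), bantam (3.43%), miR-311a (2.64%) and miR-317 (2.32%). In D. sechellia miR-10 led with 35.4% (35.31 to 35.42), ahead of miR-263a (15.6%), miR-184 (7.49%), miR-8 (5.99%), miR-312 (5.01%), let-7 (3.94%), bantam (3.84%), miR-281-2 (2.60%), miR-311 (2.57%) and miR-305 (2.35%). Intervals cover counting error only, since amplified reads are not independent molecules.

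Most microRNAs held similar shares in both libraries. Of 39 microRNAs with at least 100 RPM (reads per 1e6 microRNA reads) in 1 library and a name shared by both tables, 27 were within 2-fold. Across the 55 with reads in both, log2 levels had a Pearson r of 0.932, a correlation across microRNAs and not across samples. Higher in D. sechellia were miR-308 (129.5 against 1.34 RPM, 96.3-fold, counting interval 37.3 to 355.2, from 387 and 4 reads), miR-284 (15.7-fold, 14.4 to 17.1), miR-305 (11.9-fold, 11.5 to 12.2) and miR-10 (5.91-fold, 5.88 to 5.94). Higher in D. erecta were miR-315 (2405 against 68.9 RPM, 34.9-fold, 30.4 to 40.3) and miR-92a (5.30-fold, 4.62 to 6.08). These ratios compare the 2 libraries, not the species. The shared names give no arm, so it is assumed that a name stands for the same mature sequence in both. The miR-310 cluster, a young group whose members are named differently in each species, took 14.4% of reads in D. erecta (14.36 to 14.44) and 7.69% in D. sechellia (7.66 to 7.72). The muscle microRNAs miR-1 and miR-133 together took 0.0141% of reads in D. erecta and 0.0127% in D. sechellia, with 301 and 369 reads of miR-1 and 118 and 12 reads of miR-133 (9.88-fold higher in D. erecta, 5.45 to 19.7). In neither species do the listed microRNAs include miR-983 or the other young testis clusters, those of miR-959, miR-972 and miR-991. Their levels were therefore not analysed here, and the shares above leave them out.

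**Figure D3:**
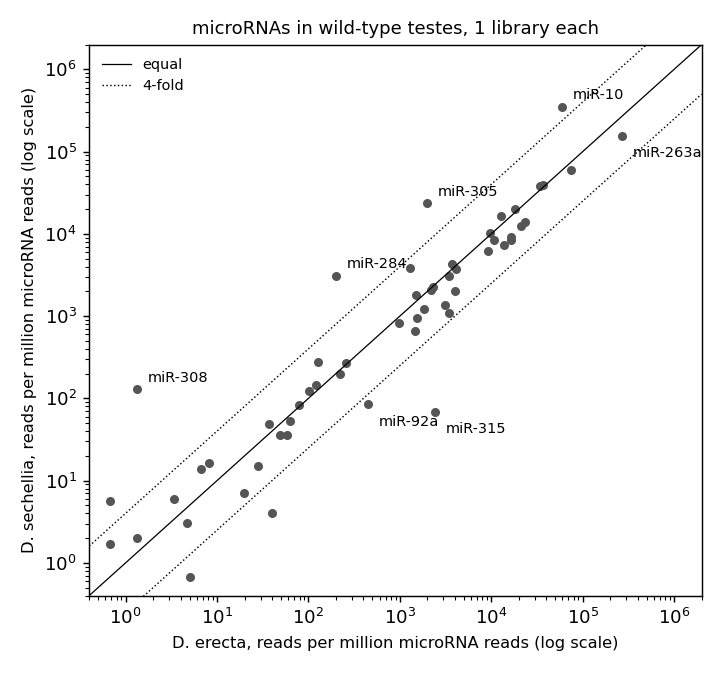
RPM of microRNAs in D. erecta (horizontal axis, log scale) and D. sechellia (vertical axis, log scale) testes for the 55 microRNAs with reads in both libraries, 1 point each; the solid line marks equal levels and dotted lines a 4-fold difference. Most points follow the equal line, and some with few reads lie outside the dotted lines; among those above 100 RPM, miR-308, miR-284, miR-305 and miR-10 lie above the upper dotted line and miR-315 and miR-92a below the lower one.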

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

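The alternatives on cyclic loess, identical values, the Hsp70 copies and deposited RPM, all reruns of the heat-shock count, the reruns of falls among targets, and the reruns of the target sets other than the block, left-out libraries, estimated correlation and fry, were chosen after seeing the data. In D. melanogaster the 167 calls became 503 with a replicate block, 32 with a 2-fold minimum, and 118 to 304 with 1 library left out; the other settings gave 122 to 172. In D. simulans the 2091 calls became 87 with a 2-fold minimum and 1241 to 2491 with 1 library left out, and a replicate block gave 2372. Same-numbered libraries deviated with a correlation of 0.147 in D. melanogaster and 0.0574 in D. simulans, over 2 pairs each, too few to tell whether the numbers mark pairs; the block changed no call of a target set. The lone library left in a group was assumed to vary like the others. The share of D. simulans calls that were higher, 54.1%, ranged from 48.2% (median ratio scaling) to 60.8% (without mutant replicate 2). Gene lists past the threshold numbered 2, and 0 with an estimated correlation and 0 with fry, and 2 to 4 with 1 library left out, where fat body was lost without mutant replicate 2 (adjusted p = 0.152). Heat-shock members lower numbered 11, 6 of 14 without the Hsp70 copies, and 9 to 12 with 1 library left out. Falls among D. simulans targets were a smaller share than among other genes under each setting but the 2-fold minimum, where this was not run (unadjusted Fisher's exact p at most 0.0356). The D. melanogaster target means turned sign, near 0: the PITA set was -0.0029 with a mean of at least 5, and with 1 library left out the 3 sets ranged from -0.0048 to 0.0313, -0.0289 to 0.0231 and -0.0137 to 0.0252. In D. simulans the 3p TargetScan set passed in limma without trend (mean difference 0.072, adjusted p = 0.0471), while after quantile normalization the 3 differences were 0.048, 0.058 and 0.038 (adjusted p 0.227, 0.154 and 0.227) and after cyclic loess 0.047, 0.057 and 0.037 (0.241, 0.157 and 0.241). With 1 library left out the 3 means ranged from 0.048 to 0.088, 0.050 to 0.093 and 0.036 to 0.077. Of 46 genes named by the rule and past the threshold, 41 kept their call under every setting other than the 2-fold minimum, which was not applied to them. The other 5 lost it in some (Hsp23, tbrd-3, tud, RpL22-like, RpL37-2). Hsp70Bb and Hsp26, named apart from the rule, are not among the 46, and their calls were not followed one by one. Genes that had not passed changed sign in 21 reruns: tbrd-1 went to 0.0117, 0.029 and 0.0096, and Obp44a to 0.0091, 0.0325 and 0.0294, under median ratio, quantile and cyclic loess scaling. With 1 library left out, tbrd-1 ranged from -0.0294 to 0.0281, Obp44a from -0.1188 to 0.1122, Obp99a from -0.0683 to 0.1139, polo from -0.0267 to 0.179, so from -0.1153 to 0.0341. Likewise up ranged from -0.0093 to 0.2895, Dso1 from -0.051 to 0.116, GstE9 from -0.4231 to 0.0088, rb from -0.0826 to 0.1519, CHOp24 from -0.1501 to 0.0907. The 6 microRNAs past 4-fold were the same 6 under each of 4 scalings. Not run were the D. simulans gene lists, the species difference, the correlation between species, and the 8mer and UTR-length settings of the seed-site search; the alternative without a filter is void. The causes of these changes were not tested.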

Other observations

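The tests in this part were chosen after the results were seen, except that leaving out a library and the estimated correlation were planned reruns. Genes without a coding function changed more often than coding genes in the D. melanogaster mutant. Of 700 tested genes annotated as other than protein-coding, 50 were called (7.14%; 27 higher, 23 lower), against 115 of 6481 protein-coding genes (1.77%; Fisher's exact test, two-sided, p = 6.68e-14). Long non-coding RNAs gave 36 of 359, pseudogenes 5 of 47 (all 5 higher) and antisense RNAs 7 of 246. Level-matched sets of coding genes gave 12.6 calls on average and at most 28. Without genes that overlap a tested neighbour the counts were 40 of 427 against 87 of 4254 (Fisher's exact test, two-sided, p = 4.71e-13).

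The D. melanogaster calls were sparse on the chromosome of the miR-983 genes and often sat beside each other elsewhere. Among the 994 tested genes on the chromosome that carries miR-983, 2 were called (CG14811 and Tsf1), against 26.6 on average in level-matched sets of other genes, and an unadjusted p under 0.05 was reached by 4.53% of them against 14.1% elsewhere. The sparseness was not particular to the locus. Among the 100 nearest genes 0 were called, where matched sets gave 0 to 6, and 4% had an unadjusted p under 0.05. Low expression was argued against, since 1 of the 800 nearest genes, most of those tested on the chromosome, was called where matched sets gave 13 to 29. Overlapping genes that share reads were argued against too. Without overlapping or heat-shock pairs, 11 pairs of adjacent genes were both called. Shuffled calls gave 3.06 on average, up to 7 in the central 95% of draws and 10 at most. Of the 11 pairs, 7 changed in the same direction. The 11 include Hsp67Bc with CG4456, which overlaps Hsp22, and the similar copies Prosalpha1 and Prosalpha1R. A candidate explanation is a hypothesis found on the same data. Under it, control and mutant stocks share the chromosome of miR-983 and differ in blocks of the others. On the other chromosomes, 65 of 354 uncalled neighbours of called genes had an unadjusted p under 0.05, where level-matched uncalled genes gave 31 to 54. Genes regulated together would also give this count, but say nothing about the few calls on the chromosome of miR-983. The 2 calls on that chromosome lie below the matched sets (18 to 36 in the central 95% of draws). This argues against an effect of miR-983 spread evenly over the chromosomes as the source of most calls. An effect of miR-983 on some of the genes stays open, as untested.

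The lower heat-shock genes in D. melanogaster mutants were weighed against 3 other explanations. Reads shared between Hsp70 copies were argued against as the whole cause, since 6 of the 14 members other than these copies also fell. A stock difference linked to these genes could not be decided. Of 22 neighbouring genes outside the list, 1 was called, CG4456, where random genes gave up to 2 in the central 95% of draws. CG4456 overlaps Hsp22 and may only share its reads. Members of the list were not counted as neighbours, although Hsp67Bc, CG4456, Hsp22 and Hsp26 are called genes next to each other in gene order. The falls of these members may therefore not be independent. A difference in handling or temperature between the dissections may also lower such genes, and cannot be told apart from genotype because both replicates of a group could have been handled together; the list mean differed by -0.47 between the groups, with both mutants below both controls. Loss of miR-983 stays open, as untested.

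The upward lean of predicted targets in D. simulans was weighed against the level-dependent shift. Against level-matched lists of other genes, the target median stood at percentile 98.61 for the 5p TargetScan set and 99.99 for the 3p set, which argues against the shift as the whole cause, and at 93.38 for the PITA set, which leaves it open there; after cyclic loess, which removes such a shift, the 3 mean differences were smaller (0.047, 0.057 and 0.037; camera adjusted p 0.241, 0.157 and 0.241). These lists treat genes as independent. The D. melanogaster 5p TargetScan set, with a median of 0.007 against -0.012 in its matched lists, reached percentile 99.64, though its camera adjusted p was 0.82. Mutant replicate 1 alone stays open, since without it the smallest of the 3 mean differences was 0.036, no larger than the gap between the mutant replicates of that set, while the other 2, 0.048 and 0.050, were above theirs with 1 mutant library left. Loss of repression by miR-983 may raise these genes. It cannot be told apart from a chance shift of correlated genes with 2 libraries per genotype (smallest camera p = 0.562 with an estimated correlation). A stock or handling difference between the groups was not tested and cannot be told apart from it either. The matched lists took account of level only, not of UTR length.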
